A study of Homo sapiens with 9 samples.

How the data were processed

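The study measured total RNA from ARPE-19 cells on 9 Affymetrix arrays, 3 each from non-treatment, LDL and ox-LDL groups, as the labels assign them. Per the labels' protocols, cells were seeded at 100000 per square centimetre, grown in 10% serum, held for 3 days in medium with 1% bovine serum albumin, and 6 micrograms of total RNA were labelled with biotin. The sample protocols state 24 hours of treatment and the series design states 48 hours.

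The deposited values were intensities on a linear scale, one signal per probe set and array; the submitters' processing notes name GCOS, the Affymetrix software, with no version in the sources used here. On each array the mean signal after trimming 2% at each end was 150.02, so the authors had scaled the arrays to a common target; no other normalization was seen, and no further scaling was applied. Detection calls were not used here. The table held 54675 probe sets, of which 62 were controls. Of the other 54613, the naming table gave 1 gene symbol for 41091, several for 1801 and none for 11721, with 19775 distinct genes. Symbols were looked up by gene ID in a RefSeq gene table (GRCh38.p14, used for names alone): 41043 were the same, 0 needed an update, and 54 IDs were not found and kept the table's symbol. No gene was named from a probe set with several symbols. No 2 arrays held identical values (0 pairs).

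A probe set entered the tests when its mean over the 9 arrays was at least 31.3, the median of those means, which left 27308. Zero values, 4 in all, were set to the lowest positive value, 0.1, before taking log2. Limma 3.58.1 in R 4.3.3 fitted a mean per group to all 9 arrays (lmFit, then eBayes with a trend of variance on mean), so that 6 residual degrees of freedom give 1 shared estimate of the spread. The 3 contrasts were LDL against non-treatment, ox-LDL against non-treatment and ox-LDL against LDL. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Signals are given as mean ± SD and log2 changes as estimate ± SE; folds are 2 to the power of the log2 change.

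Each gene was represented by its brightest probe set that entered the fit (12635 genes). Among the 6075 genes with several such probe sets, 13, 72 and 59 had probe sets moving in opposite directions, each at an unadjusted p under 0.05, in the 3 contrasts in the order above; no gene named by the rule below was among them. The negative-control level of an array was the 95th percentile of 27 unspiked bacterial control probe sets. Where a gene lay below that level on all 3 arrays of a group, its fold was replaced by a lower bound against that level. With 1 or 2 arrays of a group below it, the size of the change is uncertain.

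The gene lists, 29 in number, covered cholesterol and fatty acid synthesis, LXR and PPAR targets, lipoprotein receptors, NRF2 targets and antioxidants, unfolded protein, ATF4, heat shock, metal, NF-kB, interferon, complement, matrix, protease, TGF-beta, retinal pigment epithelium, p53, apoptosis, cell cycle, lysosome, hypoxia, respiratory chain and immediate early genes, with markers of other cell types. Lists with at least 5 measured genes, 26 of them, were tested with camera (limma) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Counts over all genes and counts adjusted over the list alone are both given for the tested lists described one by one.

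The named genes are, per contrast, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap; up to 4 members of each list described, by smallest p; and 12 genes fixed in advance whatever their result, of which 8 were measured above the filter. CD36 and OLR1 lay below the filter, and 2 of the 12 are not reported here. The fixed lists, the naming rule, the tests of the 3 contrasts and all but 1 of the alternatives were chosen before the data were examined. Some tests of explanations, and the ERK, SRF and YAP lists, were chosen later, as the closing section says. Genes called in opposite directions after LDL and ox-LDL, and PHLDA1 and DUSP4, are named because of their values.

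The procedure was tested on simulated arrays of 27308 probe sets with 100 changed at each size. For LDL against non-treatment 55% of changes of log2 1 and 83% of changes of log2 2 were recovered, with 4 false calls among 142. For ox-LDL against non-treatment the shares were 61% and 89%, with 5 false calls among 155. A simulated shift of log2 0.3 in the lysosome list over 12635 genes gave an adjusted p of 1.19e-27, and 0.000821 with an estimated correlation, and 0 of the 25 other lists were called. The simulated noise was independent between genes, whereas on the real arrays the estimated correlation reached 0.459, for the metallothionein list. The simulation therefore cannot show how often the preset test calls lists of correlated genes falsely.

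Alternatives were no filter, a filter at the 75th percentile (145.3), a pseudocount of 2.9, quantile normalization, median scaling, the replicate number as a block, fits of 2 groups alone, no variance trend, robust variance, and array weights. Others were no probe sets ending in _s_at or _x_at (which can bind several transcripts), the mean of a gene's probe sets, other thresholds, and leaving out each array in turn. A floor at the negative controls was added after the data had been seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures. The number of arrays limits the precision.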

Results

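Transcript levels were measured on 1-colour Affymetrix arrays in ARPE-19 cells, a human retinal pigment epithelial cell line, to ask how these cells respond to native and to oxidised lipoprotein. Cells had been left untreated, exposed to low density lipoprotein (LDL, the main cholesterol carrier of plasma) or exposed to oxidatively modified LDL (ox-LDL). Each of the 3 groups held 3 arrays, 9 in all. The labels call them biological replicates and say nothing more about separate cultures, so the p-values measure the spread between these samples. The sample protocols give an exposure of 24 hours and the series design gives 48 hours, a disagreement that the values could not settle; the labels give no lipoprotein dose. The median signal per array was 29.3 to 34.5, and the 95th percentile of the unspiked bacterial control probe sets, used as the negative-control level, was 17.85 to 27.12. Across arrays the correlation of log2 signals was 0.967 to 0.971 within LDL, 0.968 to 0.971 within ox-LDL and 0.952 to 0.964 within non-treatment, against 0.956 to 0.965 between non-treatment and LDL, 0.925 to 0.931 between non-treatment and ox-LDL and 0.93 to 0.934 between LDL and ox-LDL. Non-treatment replicate 3 stood apart in its RNA controls, with 18S ribosomal signals of 2950 to 4076 where the highest on any other array was 1654. Its ACTB 5' to 3' ratio was 0.612, and the lowest of the others was 0.782. Every gene named below as changed had all 3 arrays of one group above all 3 arrays of the other. The number of arrays limits the precision.

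After LDL, the genes of cholesterol synthesis fell. INSIG1, which encodes an endoplasmic reticulum protein that retains sterol-responsive transcription factors, fell 4.61-fold, from a signal of 810 ± 167 to 176 ± 36.8 (SD, n = 3 and 3; log2 change -2.20 ± 0.19 SE, limma adjusted p = 8.59e-05). IDI1, which isomerises the isoprenoid precursor, fell 3.21-fold (log2 -1.68 ± 0.12, adjusted p = 3.11e-05), although its call rested on a probe set that can bind several transcripts (log2 -0.14 and adjusted p = 0.987 without such probe sets). MSMO1, a sterol methyl oxidase, fell 3.05-fold (log2 -1.61 ± 0.11, adjusted p = 3.11e-05). ACAT2 (log2 -1.74 ± 0.16), HMGCS1 (log2 -1.39 ± 0.17), SQLE (log2 -1.34 ± 0.15), LSS (log2 -1.14 ± 0.09), FDPS (log2 -1.11 ± 0.10) and TMEM97 (log2 -0.98 ± 0.10) moved the same way with adjusted p from 7.97e-05 to 0.00179. LSS had log2 -0.68 and an adjusted p of 0.594 with the mean of its probe sets, and SQLE an adjusted p of 0.0747 without a variance trend. The list of cholesterol synthesis and SREBP2 targets had 19 measured genes and a median log2 change of -0.98. In this list 11 genes fell, 16 when adjusted over the list alone, and none rose in either count. Its camera test gave an adjusted p of 1.22e-43, and 0.000125 with an estimated correlation. Among fatty acid genes, SCD fell 1.52-fold (log2 -0.60 ± 0.09, adjusted p = 0.00891), FADS2 fell 1.72-fold (log2 -0.78 ± 0.12, adjusted p = 0.0172) and FASN fell 1.70-fold (log2 -0.76 ± 0.13, adjusted p = 0.0243). These 3 calls depended on single arrays. Without LDL replicate 1 the adjusted p was 0.0684 for SCD, 0.103 for FADS2 and 0.103 for FASN. Without LDL replicate 2 it was 0.129 for FADS2 and 0.156 for FASN. FADS2 also missed at 0.0814 without non-treatment replicate 1, and FASN at 0.0895 without non-treatment replicate 2 and 0.101 without LDL replicate 3. Over the alternatives the adjusted p ranged from 0.00228 to 0.792 for SCD, from 0.00569 to 0.138 for FADS2 and from 0.00568 to 0.201 for FASN. The list of fatty acid synthesis and SREBP1 targets (14 genes, median log2 -0.21) had an adjusted p of 0.0004, which became 0.184 with an estimated correlation and 0.855 without _s_at and _x_at probe sets. In it 3 genes fell, 3 also when adjusted over the list alone, where 1 rose.

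**Figure D1:**
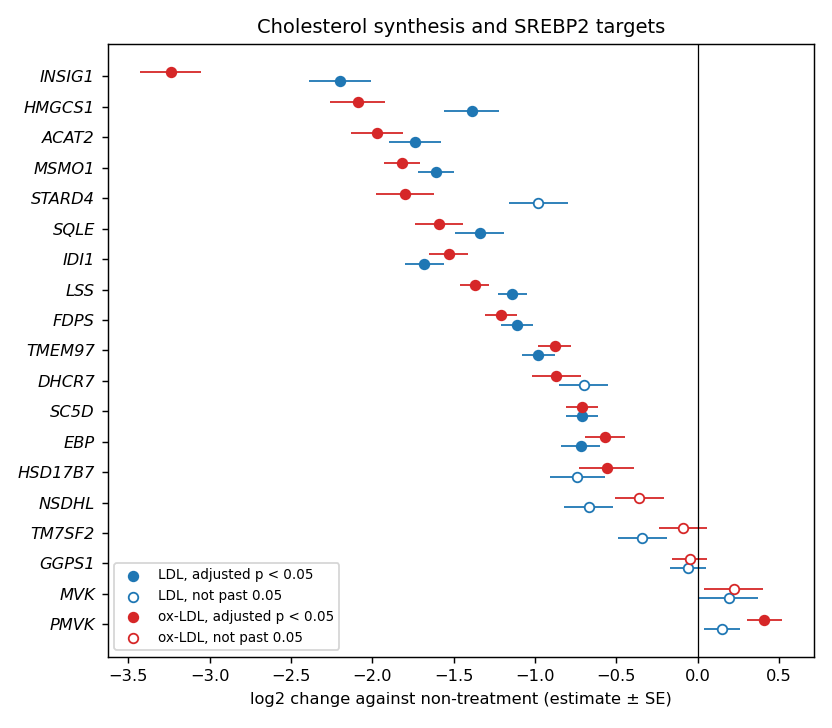
Log2 change against non-treatment (horizontal axis) of the 19 measured cholesterol synthesis genes after LDL (blue) and ox-LDL (red), with bars of 1 SE; filled points had an adjusted p under 0.05. INSIG1 lies at -2.20 after LDL and at -3.24 after ox-LDL.

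Some genes rose after LDL. SFRP4, a secreted WNT-binding protein, rose 4.92-fold, from 105 ± 7.7 to 517 ± 32.1 (SD, n = 3 and 3; log2 2.30 ± 0.18, adjusted p = 6.65e-05). TFPI2, a protease inhibitor, rose 2.47-fold (log2 1.30 ± 0.10, adjusted p = 6.65e-05) and DHRS3, a retinal-reducing enzyme, rose 2.31-fold (log2 1.21 ± 0.13, adjusted p = 0.000602). The quinone reductase NQO1 rose 1.90-fold (log2 0.92 ± 0.10, adjusted p = 0.000583, and 0.0557 without a variance trend). The cholesterol exporter ABCA1 rose 1.93-fold (log2 0.95 ± 0.14, adjusted p = 0.00992, but 0.0554 without LDL replicate 1 and 0.154 in a fit of 2 groups alone). The haem oxygenase HMOX1 rose 1.80-fold (log2 0.85 ± 0.12, adjusted p = 0.00773, but 0.0542 and 0.0502 without LDL replicates 1 and 2 and 0.132 without a variance trend). ADAMTS15, IGFBP6, GNG11, LXN, STAM2 and EPDR1 rose by log2 0.55 to 0.78. All 6 missed the threshold without LDL replicate 2, with adjusted p of 0.219, 0.102, 0.0972, 0.0686, 0.156 and 0.19 in that order. Each also missed it without other single arrays. GNG11 and LXN missed without non-treatment replicate 1 or LDL replicate 1, and STAM2 without non-treatment replicate 1 or LDL replicate 3. ADAMTS15, IGFBP6 and EPDR1 missed without any 1 LDL array and without some others, for IGFBP6 any 1 ox-LDL array. CTHRC1, a collagen-associated secreted protein, fell by 0.91 on the log2 scale (± 0.10, adjusted p = 0.00107, and 0.0557 without a variance trend). CTSV, a lysosomal cysteine protease, fell by 1.02 (± 0.17, adjusted p = 0.0302). ADAM33 fell by 1.93 (± 0.32, adjusted p = 0.0243), with 1 LDL array below the negative controls, so its size is uncertain. ADAM33 missed at 0.107, 0.0976, 0.106 and 0.105 without non-treatment replicates 1 and 2 and LDL replicates 1 and 3. CTSV missed at 0.192, 0.157 and 0.053 without LDL replicates 1, 2 and 3, and at up to 0.0582 when any 1 of the ox-LDL arrays was left out. Across all alternative settings, the adjusted p of the 10 named genes that lost a call on leaving out 1 array ranged from 0.0008 to 0.802.

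For LDL against non-treatment, limma called 68 of 27308 probe sets at a Benjamini-Hochberg adjusted p under 0.05, 23 higher and 45 lower, which is 0.25% of those tested. The count was 43 without LDL replicate 1, 39 without LDL replicate 2, 91 without non-treatment replicate 3 and 22 without a variance trend. At the level of genes, 40 of 12635 changed, 13 higher and 27 lower, of which 3 rose and 10 fell at least 2-fold. An unadjusted p under 0.05, which chance alone would give for a share of 0.05, was found for 1752 of the 27308 probe sets. The 2 groups did not overlap for 11.2% of genes, where chance gives 10%. Of 26 gene lists tested, 5 passed camera with its preset correlation. The NRF2 targets and antioxidant defence list rose (24 genes, median log2 0.18, adjusted p = 4.33e-10, and 0.0248 with an estimated correlation; 2 genes rose, 6 when adjusted over the list alone). The cell cycle and proliferation list rose too (25 genes, median log2 0.18, adjusted p = 1.23e-05, and 0.0521 with an estimated correlation; no gene past the threshold in either count). The list of general antioxidant enzymes passed with a median of 0.10 (20 genes, adjusted p = 0.00814, and 0.445 with an estimated correlation), with no member past the threshold in either count. Its adjusted p was 0.126, 0.0749 and 0.199 without non-treatment replicate 2, non-treatment replicate 3 and LDL replicate 1, and 0.385 with fry. The other 21 lists had adjusted p from 0.0887 to 0.952. PLIN2, the lipid droplet coat protein, was not called after LDL (log2 -0.01, 95% confidence interval -0.18 to 0.15, adjusted p = 0.99). Other genes fixed in advance were not called either: VEGFA (log2 0.05 ± 0.07), CXCL8 (log2 0.27 ± 0.40), ABCG1 (log2 -0.22 ± 0.37) and DDIT3 (log2 -0.06 ± 0.17).

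After ox-LDL, lipid handling genes moved in opposing directions. ABCA1 rose 16.6-fold, from 67.4 ± 2.9 to 1127 ± 156 (SD, n = 3 and 3; log2 4.06 ± 0.14, adjusted p = 6.3e-10). PLIN2 rose 4.21-fold, from 2735 ± 217 to 11487 ± 401 (log2 2.07 ± 0.08, adjusted p = 9.91e-10). With the mean of its probe sets the PLIN2 change was log2 1.03 (adjusted p = 0.00446). ANGPTL4, a secreted lipase inhibitor, rose 5.06-fold (log2 2.34 ± 0.16, adjusted p = 3.19e-07), and PDK4, which limits glucose oxidation, rose 3.28-fold (log2 1.71 ± 0.20, adjusted p = 3.71e-05). INSIG1 fell 9.43-fold (log2 -3.24 ± 0.19, adjusted p = 5.31e-08). MSMO1 fell 3.53-fold (log2 -1.82 ± 0.11), IDI1 2.89-fold (log2 -1.53 ± 0.12, adjusted p = 0.276 without _s_at and _x_at probe sets) and LSS 2.59-fold (log2 -1.37 ± 0.09). In the cholesterol list 14 of 19 genes fell and 1 rose, 15 and 1 when adjusted over the list alone. The list fell as a whole (median log2 -0.88, camera adjusted p = 1.97e-10, and 0.00596 with an estimated correlation). LXR targets and cholesterol efflux rose (5 of 10 genes, 6 when adjusted over the list alone, median log2 0.61, and 1.1 without _s_at and _x_at probe sets, adjusted p = 0.00173, but 0.0668 with an estimated correlation). MYLIP was up 2.85-fold (log2 1.51, and 1 with the mean of its probe sets), SMPDL3A 3.15-fold and PLTP 1.55-fold. PPAR targets and fatty acid oxidation rose (10 of 16 genes in both counts, median log2 0.42, and 0.2 without _s_at and _x_at probe sets, adjusted p = 3.45e-06, but 0.0568 with an estimated correlation). The fatty acid synthesis list did not pass (3 of 14 genes rose and 5 fell, 3 and 8 when adjusted over the list alone, adjusted p = 0.191). Within it ELOVL6 rose by log2 1.07 and ME1 by 0.78, while FASN fell by 0.89 and FADS2 fell by 0.82. Lipoprotein and scavenger receptors did not pass (2 of 12 genes rose and 2 fell in both counts, median log2 0.07, adjusted p = 0.699), although LRP8 rose 4.79-fold and SCARB1 fell 1.51-fold. ABCG1 was not called (log2 -0.73 ± 0.37, adjusted p = 0.205).

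Antioxidant genes rose after ox-LDL. NQO1 rose 16-fold, from 402 ± 44.9 to 6410 ± 538 (SD, n = 3 and 3; log2 4 ± 0.10, adjusted p = 4.33e-11). The conjugate exporter ABCC3 rose 13.8-fold (log2 3.79 ± 0.18, adjusted p = 8.49e-09; log2 2.52 with the mean of its probe sets), the cystine transporter SLC7A11 rose 8.62-fold (log2 3.11 ± 0.15, adjusted p = 9.23e-09), and HMOX1 rose 7.80-fold (log2 2.96 ± 0.12, adjusted p = 2.3e-09). Of 24 NRF2 targets 19 rose, 21 when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 8.83e-17, and 0.00596 with an estimated correlation). General antioxidant enzymes rose (13 of 20 genes, 15 when adjusted over the list alone, median log2 0.41, adjusted p = 2.02e-07, but 0.0749 with an estimated correlation). Among them were SOD3 2.88-fold, SOD2 2.78-fold and CAT 2.19-fold. The metallothionein and zinc response list rose with a median of 2.23 (6 of 7 genes higher in both counts, camera adjusted p = 1.76e-08, but 0.0668 with an estimated correlation). All 6 were metallothioneins, which bind zinc and copper. The 1 measured gene of another kind was lower, so the rise covers metallothioneins only. MT1G rose 5.42-fold (log2 2.44 ± 0.08, adjusted p = 6.3e-10) and MT2A 4.02-fold (log2 2.01 ± 0.09, adjusted p = 9.23e-09). Metallothioneins are near-identical in sequence and may share probes, so single members are uncertain.

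Cytokine and immune genes rose after ox-LDL. IL33, an alarm cytokine, rose from 24.2 ± 15.2 to 855 ± 167 (n = 3 and 3; log2 5.32 ± 0.39, adjusted p = 5.24e-07), and CXCL8, a neutrophil attractant, from 25.8 ± 9.3 to 218 ± 94.4 (n = 3 and 3; log2 3.02 ± 0.40, adjusted p = 0.000112). For both, 2 of the 3 non-treatment arrays lay below the negative controls, so the size of the rise is uncertain. The adhesion molecule ICAM1 rose 2.58-fold (log2 1.37 ± 0.18, adjusted p = 0.000136), and the chitinase-like protein CHI3L1 rose 16.2-fold (log2 4.02 ± 0.15, adjusted p = 9.53e-10). In the NF-kB targets and cytokines list 8 of 14 genes rose and 1 fell, 11 and 1 when adjusted over the list alone (median log2 0.79, adjusted p = 0.000234, but 0.141 with an estimated correlation). With no filter its median was 0.42, and with the filter at the 75th percentile its adjusted p was 0.13. The interferon response rose (6 of 17 genes with 1 lower, 8 and 1 when adjusted over the list alone, median log2 0.60, adjusted p = 0.00173, but 0.141 with an estimated correlation). IFIT3 rose most, 4.65-fold (log2 2.22 ± 0.12, adjusted p = 2.82e-08). The call of IRF1 (log2 0.87 ± 0.22, adjusted p = 0.013) was lost without non-treatment replicate 1 and without ox-LDL replicate 1, at 0.0544 and 0.0676, in a range of 0.000584 to 0.0676 over the alternatives. Complement and its regulators rose (4 of 12 genes in both counts, median log2 0.34, adjusted p = 0.00228, but 0.0607 with an estimated correlation). C1S was up 2.37-fold, C1R 1.68-fold, CLU 1.76-fold and CD59 1.71-fold (log2 0.78, and 0.49 without _s_at and _x_at probe sets).

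Matrix genes and markers of the TGF-beta response fell after ox-LDL. TAGLN, an actin-binding protein of smooth muscle, fell 14.2-fold, from 5903 ± 769 to 422 ± 108 (SD, n = 3 and 3; log2 -3.83 ± 0.15, adjusted p = 2.1e-09). Without _s_at and _x_at probe sets, where another probe set stood for it, the TAGLN change was log2 -1.51 (adjusted p = 3.21e-05). ACTA2, smooth muscle actin, fell 4.16-fold (log2 -2.06 ± 0.08, adjusted p = 1.73e-09). The basement membrane collagen COL4A1 fell 3.82-fold, from 5213 ± 488 to 1360 ± 55.7 (log2 -1.93 ± 0.08, adjusted p = 2.32e-09). COL1A1 fell 4.11-fold (log2 -2.04 ± 0.12, adjusted p = 7.28e-08). TGFB2 fell 3.70-fold (log2 -1.89 ± 0.09, adjusted p = 9.57e-09) and CCN2, a matricellular growth factor, 3.17-fold (log2 -1.66 ± 0.09, adjusted p = 3.72e-08). TGF-beta response and mesenchymal markers fell (11 of 18 genes lower and 3 higher, 13 and 3 when adjusted over the list alone, median log2 -0.45, adjusted p = 7.64e-06, but 0.0568 with an estimated correlation). Extracellular matrix and basement membrane genes fell (14 of 26 lower and 3 higher, 15 and 3 when adjusted over the list alone, median log2 -0.52, adjusted p = 8.8e-06, but 0.0749 with an estimated correlation). Matrix proteases and inhibitors went both ways, 7 of 20 up and 8 down in both counts (adjusted p = 0.951). SERPINE2 rose 8.46-fold (log2 3.08 ± 0.10) and TIMP1 2.51-fold, while ADAMTS5 fell 13.8-fold (log2 -3.79 ± 0.20) and TIMP3 fell 2.10-fold.

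The largest changes after ox-LDL lay partly outside the fixed lists. IL13RA2, a decoy receptor for interleukin 13, rose 47.3-fold (log2 5.56 ± 0.27, adjusted p = 1.09e-08). DUSP6, a phosphatase of ERK kinases, rose 28-fold (log2 4.81 ± 0.27, adjusted p = 3.97e-08), and SLCO4A1, an organic anion transporter, rose 25.6-fold (log2 4.68 ± 0.23, adjusted p = 1.6e-08). IQGAP2 (log2 4.88 ± 0.91), RGS17 (log2 3.85 ± 0.25) and CLMP (log2 3.81 ± 0.16) also rose, and 2 non-treatment arrays for IQGAP2 and 1 for RGS17 were below the negative controls. NRP1 and GPAT3 lay below the negative controls on all non-treatment arrays and were at least 4.31-fold and 3.86-fold higher. The call of NRP1 was lost without ox-LDL replicate 1 (adjusted p = 0.0756) and that of GPAT3 without ox-LDL replicate 3 (adjusted p = 0.0505). Over the alternatives the adjusted p of these genes ranged from 4.3e-05 to 0.0756. NPPB, the B-type natriuretic peptide precursor, fell 35.6-fold (log2 -5.15 ± 0.14, adjusted p = 8.8e-11). MGP, an inhibitor of calcification, fell 21.6-fold (log2 -4.43 ± 0.19, adjusted p = 3.94e-09). TGM1 and RASGRP1 fell by 4.37 and fell by 4.03 on the log2 scale, with 1 and 2 ox-LDL arrays below the negative controls; with a floor at that level RASGRP1 had log2 -2.48. KRT33A fell by 4.76 (± 0.12), but hair keratins are near-identical and may share probes. Below the negative controls on all ox-LDL arrays, with lower bounds in place of folds, were SYTL5 (at least 19.4-fold lower), MYOZ2 (at least 10.8-fold), MFAP4 (at least 10.7-fold), TNNC1 (at least 6.68-fold), HSPB3 (at least 5.77-fold), PLAC9 (at least 5.14-fold) and LINC01133 (at least 3.62-fold).

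Stress, organelle and growth genes gave smaller or mixed changes after ox-LDL. Lysosome and autophagy genes rose (12 of 24, 13 with 1 lower when adjusted over the list alone, median log2 0.30, adjusted p = 1.44e-05, but 0.0668 with an estimated correlation). The protease CTSD rose 2.91-fold (log2 1.54 ± 0.08, adjusted p = 2.23e-08) and the autophagy receptor SQSTM1 2.15-fold (log2 1.11 ± 0.08, adjusted p = 5.64e-07; log2 0.74 without _s_at and _x_at probe sets). The ATF4 and integrated stress response list rose (6 of 20 genes with 2 lower, 9 and 2 when adjusted over the list alone, median log2 0.18, adjusted p = 0.0223, but 0.0749 with an estimated correlation). Its members TRIB3 rose 4.29-fold and SLC7A5 fell 2.17-fold. VEGFA fell 1.46-fold (log2 -0.55 ± 0.07, adjusted p = 0.000109, and 0.0684 with the mean of its probe sets). DDIT3 was not called (log2 -0.03 ± 0.17, adjusted p = 0.936). The unfolded protein response fell slightly (4 of 20 genes in both counts, median log2 -0.17, adjusted p = 0.0333, but 0.141 with an estimated correlation). Its call was lost without non-treatment replicate 3 (adjusted p = 0.0561), without ox-LDL replicate 3 (adjusted p = 0.0568) and with the filter at the 75th percentile (adjusted p = 0.071). HSPA5, its central chaperone, fell 1.31-fold (log2 -0.39 ± 0.06, adjusted p = 0.000761; log2 -0.63 with the mean of its probe sets). Immediate early genes rose (7 of 14 with 3 lower, 9 and 3 when adjusted over the list alone, median log2 0.55, adjusted p = 0.0245, but 0.33 with an estimated correlation, 0.0842 without non-treatment replicate 3 and 0.134 with the filter at the 75th percentile). KLF4 was up 5.03-fold and FOSL1 3.68-fold. The p53 targets fell (8 of 16 with 1 higher, 10 and 1 when adjusted over the list alone, median log2 -0.35, adjusted p = 0.00123, but 0.0568 with an estimated correlation). ZMAT3 was down 1.93-fold and PMAIP1 up 3.56-fold.

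After ox-LDL no shift was called for hypoxia and angiogenesis (3 of 19 genes higher and 7 lower in both counts, median log2 -0.12, adjusted p = 0.472). Apoptosis regulators did not pass (4 of 23 higher and 3 lower, 5 and 4 when adjusted over the list alone, median 0.03, adjusted p = 0.643), nor did cell cycle and proliferation (2 of 25 higher and 1 lower in both counts, 0.08, adjusted p = 0.643). The heat shock response did not pass (1 of 13 higher and 1 lower, 1 and 2 when adjusted over the list alone, 0.03, adjusted p = 0.951). The mitochondrial respiratory chain (3 of 22 higher and none lower, none either way when adjusted over the list alone, 0.06, adjusted p = 0.191) and retinal pigment epithelium markers (2 of 16 higher and 4 lower in both counts, -0.01, adjusted p = 0.282) did not pass either. Single members did change. FGF2, a growth factor of the hypoxia list, fell 2.05-fold (log2 -1.04 ± 0.10, adjusted p = 8.53e-06). EPAS1, an oxygen-sensitive transcription factor, rose 2.78-fold (log2 1.48 ± 0.07, adjusted p = 1.03e-08), and CCNA2, a cyclin, fell 2.63-fold (log2 -1.39 ± 0.12, adjusted p = 3.07e-06). KRT8 fell 2.37-fold (log2 -1.24 ± 0.09, adjusted p = 2.9e-07), and MITF, a pigment cell transcription factor, fell 2.16-fold (log2 -1.11 ± 0.12, adjusted p = 1.57e-05). In marker lists of other cell types, fibroblast markers did not pass (1 of 7 genes higher and 2 lower in both counts, median log2 -0.15, adjusted p = 0.387). Too few genes were measured to test myeloid markers (3 genes, 1 called lower, median log2 -0.55) or retinal neuron and glia markers (4 genes, 1 called lower, median log2 -0.21). The same held for endothelial markers (1 gene, PECAM1, not called over all genes, log2 0.43).

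**Figure D2:**
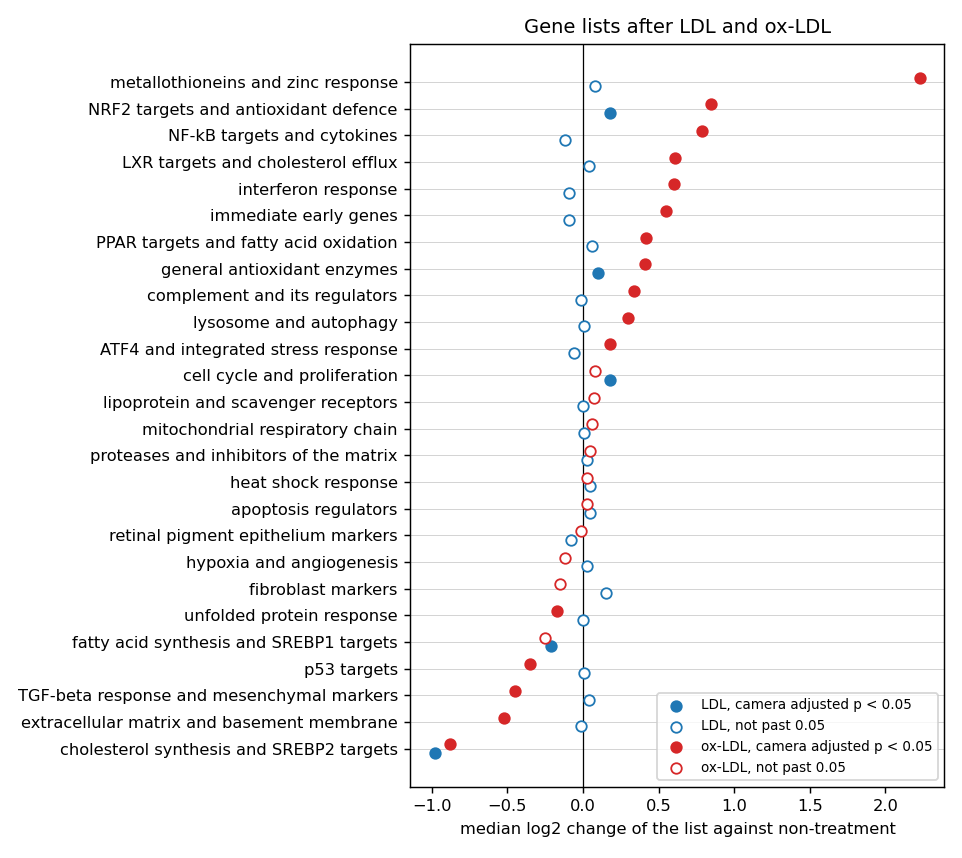
Median log2 change against non-treatment (horizontal axis) of each tested gene list after LDL (blue) and ox-LDL (red); filled points had a camera adjusted p under 0.05 with the preset correlation. The metallothioneins lie highest after ox-LDL at 2.23 and the cholesterol list lowest, at -0.88 after ox-LDL and -0.98 after LDL.

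For ox-LDL against non-treatment, limma called 4982 probe sets, 2451 higher and 2531 lower, which is 18.24% of those tested. In genes the count was 2872, with 1442 higher and 1430 lower; 354 rose and 393 fell at least 2-fold. The 2 groups did not overlap for 38.5% of genes, where chance gives 10%. Of 26 lists 16 passed camera with its preset correlation, 11 up and 5 down, and 2 of these (cholesterol synthesis and NRF2 targets) passed with an estimated correlation. Median, mean and test differed in sign for the heat shock, protease and hypoxia lists here, and after LDL for the LXR, unfolded protein, complement, matrix, protease and p53 lists, none of which passed. The labels name no batch or processing day, so a batch shared by a group's 3 arrays and the treatment cannot be told apart.

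Set directly against LDL, ABCA1 was 8.61-fold higher after ox-LDL (1127 ± 156 against 131 ± 19.3, SD, n = 3 and 3; log2 3.11 ± 0.14, adjusted p = 5.78e-09). PLIN2 was 4.25-fold higher (log2 2.09 ± 0.08, adjusted p = 8.75e-10; log2 1.21 with the mean of its probe sets), NQO1 8.41-fold higher (log2 3.07 ± 0.10, adjusted p = 3.24e-10) and HMOX1 4.34-fold higher (log2 2.12 ± 0.12, adjusted p = 4.73e-08). COL4A1 was 4.49-fold lower (log2 -2.17 ± 0.08, adjusted p = 8.71e-10), TAGLN 13.7-fold lower (log2 -3.78 ± 0.15, adjusted p = 2.36e-09; log2 -1.16 without _s_at and _x_at probe sets) and VEGFA 1.52-fold lower (log2 -0.60 ± 0.07, adjusted p = 4.72e-05). The chemokine receptor CXCR4 was 14.2-fold higher (log2 3.83 ± 0.09, adjusted p = 9.68e-11) and HMGA2, a chromatin architectural protein, 18.3-fold higher (log2 4.19 ± 0.16, adjusted p = 1.2e-09). Without _s_at and _x_at probe sets HMGA2 had log2 2.39 (adjusted p = 0.00176). The endothelin EDN2 was 15.6-fold lower (log2 -3.97 ± 0.17, adjusted p = 4.31e-09). INSIG1 was 2.05-fold lower (log2 -1.03 ± 0.19, adjusted p = 0.00135), STARD4 1.76-fold lower (log2 -0.82 ± 0.18, adjusted p = 0.00693) and HMGCS1 1.63-fold lower (log2 -0.70 ± 0.17, adjusted p = 0.00957). The cholesterol list as a whole did not differ detectably (3 of 19 genes lower, also when adjusted over the list alone, median log2 0.00, adjusted p = 0.425). IL13RA2 (log2 6.4 ± 0.27), DUSP6 (log2 5.46 ± 0.27), SLCO4A1 (log2 5.17 ± 0.23), IL33 (log2 5.11 ± 0.39), CHI3L1 (log2 4.02 ± 0.15), RGS17 (log2 4 ± 0.25) and IQGAP2 (log2 3.91 ± 0.91) were higher. There were 1 or 2 LDL arrays below the negative controls for IL13RA2, DUSP6, IL33, RGS17 and IQGAP2. ATP6V1C2, NRP1 and GPAT3 were at least 5.96-fold, 5.21-fold and 4.67-fold higher. NRP1 lost its call without LDL replicate 3 or any 1 ox-LDL array (adjusted p up to 0.177, without ox-LDL replicate 1). GPAT3 lost its call without any 1 LDL or ox-LDL array (adjusted p up to 0.293, without ox-LDL replicate 3). Their adjusted p over the alternatives ranged from 1.73e-05 to 0.293.

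Among the largest falls against LDL were NPPB (log2 -5.57 ± 0.14), TGM1 (log2 -4.58 ± 0.34), RASGRP1 (log2 -4.57 ± 0.74), KRT33A (log2 -4.43 ± 0.12), MGP (log2 -4.28 ± 0.19) and KRT13 (log2 -4.08 ± 0.48). Of these, 1 ox-LDL array for TGM1 and 2 each for RASGRP1 and KRT13 lay below the negative controls, and with a floor there RASGRP1 had log2 -3.03. SYTL5, MFAP4, TNNC1, PLAC9 and RASGRF1, below the negative controls on all ox-LDL arrays, were at least 17.9-fold, 13.7-fold, 4.99-fold, 4.53-fold and 3.34-fold lower. NRF2 targets were higher (16 of 24 genes with 1 lower in both counts, median log2 0.79, adjusted p = 1.42e-11, and 0.0322 with an estimated correlation). The metallothionein and zinc list was higher too (6 of 7 in both counts, median log2 1.92, adjusted p = 1.23e-08, but 0.082 with an estimated correlation), and so were NF-kB targets (10 of 14 with 1 lower, 11 and 1 when adjusted over the list alone, median log2 0.98, adjusted p = 0.000124, but 0.133 with an estimated correlation). With no filter the NF-kB median was 0.37, and with the filter at the 75th percentile the adjusted p was 0.123. TGF-beta response genes were lower (12 of 18 with 3 higher in both counts, median log2 -0.63, adjusted p = 5.12e-06, but 0.082 with an estimated correlation). Across the comparison, limma called 4937 probe sets, 2409 higher and 2528 lower, or 2811 genes, 1436 higher and 1375 lower. The groups did not overlap for 41.2% of genes, where chance gives 10%. Of 26 lists 15 passed, 11 up and 4 down, and the NRF2 targets alone passed with an estimated correlation. The unfolded protein response was among the 4 lower lists (4 of 20 genes lower, 5 when adjusted over the list alone, median log2 -0.17, adjusted p = 0.0287, but 0.133 with an estimated correlation). It lost its call without LDL replicate 2 (adjusted p = 0.0821), without ox-LDL replicate 3 (adjusted p = 0.0501) and with the filter at the 75th percentile (adjusted p = 0.068). Median, mean and test differed in sign for the fatty acid synthesis, retinal pigment epithelium and hypoxia lists, none of which passed.

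**Figure D3:**
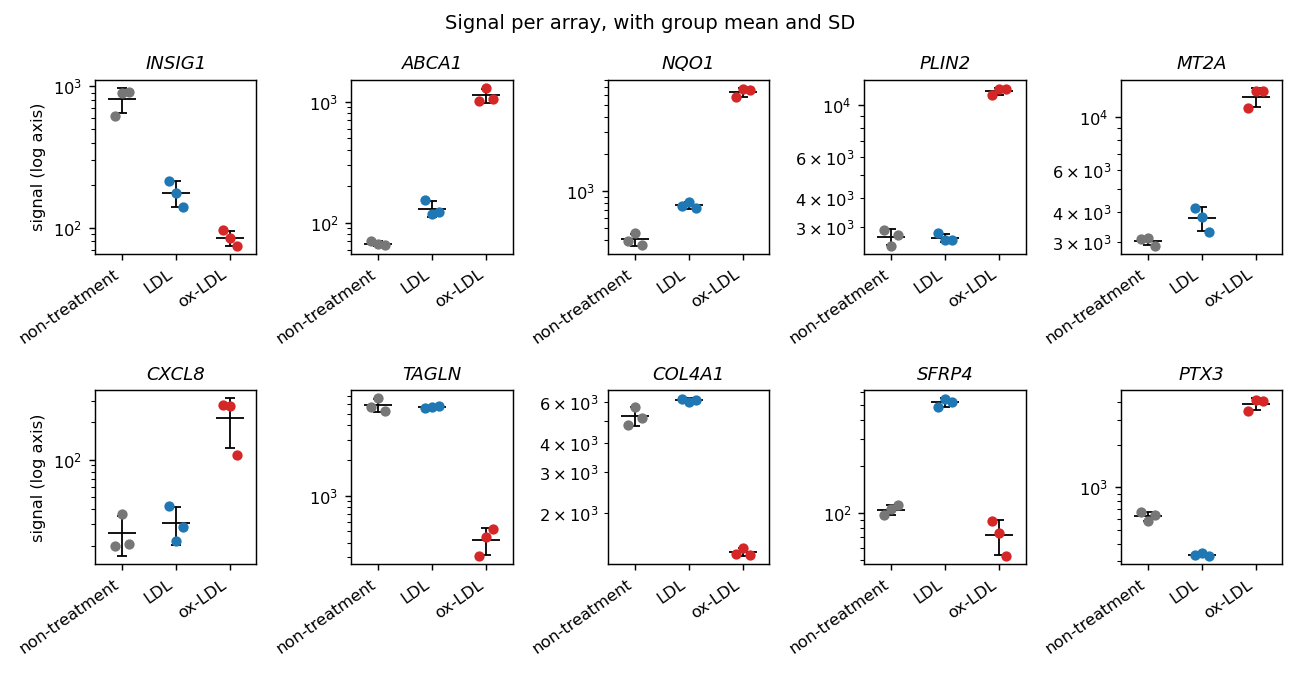
Signal per array on a log axis for 10 genes in the 3 groups, with a bar at the mean of 3 arrays and error bars of 1 SD. INSIG1 fell in both treated groups, SFRP4 rose after LDL to 517, and ABCA1, NQO1 and PLIN2 were highest after ox-LDL.

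Because both treatments were set against the same non-treatment arrays, their overlap was compared with simulated unchanged groups. Of the 40 genes called after LDL, 27 were called in the same direction after ox-LDL, 9 in the opposite direction and 4 were not called. The INSIG1, MSMO1 and IDI1 calls were among the shared falls, and 11 of the 27 genes lower after LDL belonged to the cholesterol list. In probe sets, 16 were higher and 33 lower in both comparisons, where independent lists would share 2.06 and 4.17. In 20 simulations of unchanged groups against the same controls 0 probe sets were called. Lists of the observed sizes, taken by p from these simulations, shared 17 and 31.35 probe sets on average and 21 and 36 at most. Those simulated lists held noise alone, whereas the real lists held called probe sets. This comparison therefore cannot decide how much of the overlap is a shared effect. Over all 27308 probe sets the log2 changes correlated at 0.277, and at 0.5 in the simulated unchanged groups; the covariance was 0.0508, against 0.0436 simulated, a difference of 0.0072. The correlation is across probe sets, which are not independent replicates. The 3 non-treatment arrays are too few to split, so part of the overlap may come from the shared controls.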

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

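The test of non-treatment replicate 3 was chosen after the result it weighs had been seen, as was the test of the scaling; the RNA quality test was set before its value was seen but replaced an earlier one, on the 5' to 3' ratios of the ox-LDL arrays, that had been seen, and the others were set before.

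The LDL response was narrow, with 68 probe sets called. Leaving out non-treatment replicate 3, whose RNA controls stood apart, multiplied the count by 1.34, to 91. Without non-treatment replicates 1 and 2 the count was 52 and 60, so losing a control array also costs calls. The fit without replicate 3 still called 5016 probe sets for ox-LDL against non-treatment. That array therefore did not hide an LDL response as broad and as large as that to ox-LDL. With 2 control arrays left, the fit cannot exclude that it hid a broad response of smaller changes. The share of changed probe sets, called or not, as estimated from the p-values was 5.8% for LDL and 43.7% for ox-LDL. The ratio was 0.133 (0.019 to 0.282 on leaving out single arrays). This argues against a missed response as broad as that to ox-LDL and with changes of like size. Small changes lower the estimate too, so it cannot exclude a broad response of smaller changes that 3 arrays a group had missed. Among the 10 splits of the 6 arrays, too few for a share under 0.05, 1 gave as many called probe sets (real 68, highest other 0) and 2 gave as many lists (real 5, highest other 6). A weaker biological effect of native LDL, a short exposure or a low dose stays open, and none of these was tested.

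The ox-LDL response was broad, with 4982 probe sets called against non-treatment and 4937 against LDL. After quantile normalization 98.1% of the calls against non-treatment were kept in the same direction. Most calls thus did not depend on the choice between quantile normalization and the deposited scaling. Both bring the arrays to a common level, so this test cannot exclude calls that such scaling created. For RNA quality, the deviation of non-treatment replicate 3 from its 2 fellow arrays was set beside the ox-LDL minus LDL change. Over the 4937 probe sets called between ox-LDL and LDL they correlated at -0.049 (-0.053 to -0.046 on leaving out single LDL or ox-LDL arrays). The change thus did not follow that array's deviation. The deviation holds the noise of 1 array, which pulls a correlation toward 0, so this cannot exclude that RNA quality contributed to some calls. An unrecorded day or batch shared by the 3 ox-LDL samples may have contributed and cannot be told apart from the treatment, since the 18 hybridization spike controls (median log2 difference -0.03, SD 0.06) do not cover culture and RNA steps. The 10 splits are too few for a share under 0.05: against non-treatment 1 gave as many probe sets (real 4982, highest other 0) and 1 as many lists (real 16, highest other 9), and against LDL 1 gave as many probe sets (real 4937, highest other 0) and 1 as many lists (real 15, highest other 10).

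Between the treatments, 9 genes were called in opposite directions against non-treatment, with a direct test of ox-LDL minus LDL on the log2 scale of 3.54 for PTX3, -2.87 for SFRP4, -2.61 for ADAMTS15, 2.35 for FIBIN, -2.03 for CHST2, 1.91 for KHDRBS3, 1.67 for CYP1B1, 1.40 for CPA4 and 1.02 for KLF6 (adjusted p from 9.75e-11 to 1.51e-05). The 9 were selected for opposite calls and a called direct test, so that test gives their sizes and no further support. PTX3, a secreted pattern recognition protein, fell after LDL (log2 -0.90 ± 0.09, adjusted p = 0.000466) and rose after ox-LDL (log2 2.64 ± 0.09, adjusted p = 6.8e-10), and all non-treatment arrays lay between the groups for each of the 9. When single non-treatment arrays were left out, all 9 genes still had opposite directions, an outcome fixed by that position which decides nothing; both calls were kept for 3, 4 and 4 genes without non-treatment replicates 1, 2 and 3. PTX3 and FIBIN kept both calls in all 9 fits without 1 array. FIBIN still lost its LDL call without a variance trend (adjusted p = 0.0874) and with 2 groups alone. The LDL call was lost without LDL replicate 2 for ADAMTS15 (adjusted p = 0.219), CHST2 (0.23), KHDRBS3 (0.0902), CYP1B1 (0.0629), CPA4 (0.184) and KLF6 (0.156). For KHDRBS3 and CPA4 it was lost without any 1 of the 9 arrays, and for CHST2 without any 1 but non-treatment replicate 2. For ADAMTS15 and KLF6 it was lost without several other arrays too. The ox-LDL call was lost for SFRP4 without any 1 array but ox-LDL replicate 1 (up to 0.148). For KLF6 it was lost without non-treatment replicates 2 or 3 or any 1 ox-LDL array (up to 0.0964). Calls of KLF6, KHDRBS3 and CYP1B1 were also lost under other choices of probe set. A biological difference between native and oxidised lipoprotein stays open beside an unrecorded batch.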

How the results depend on the processing

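The floor at the negative controls was chosen after the data had been seen; the other alternatives here were planned.

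Of 26 alternative settings, 9 of which left out 1 array each, 20 to 22 gave a value for a given gene. Of the 238 called gene results selected by the naming rule or for their values, 197 kept their direction and call under all that gave a value, and 41 lost the call under some. No called gene or list reversed. Of 36 called list results, 31 lost the call with an estimated correlation; under the other alternatives 28 were kept throughout, with adjusted p of 9.64e-46 to 0.0469, and 8 were lost under some, with adjusted p of 2.39e-05 to 0.855.

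With an estimated correlation, 2, 2 and 1 lists passed for LDL against non-treatment, ox-LDL against non-treatment and ox-LDL against LDL. The preset correlation had given 5, 16 and 15. The p53, ATF4 and complement lists lost their ox-LDL calls with estimates of 0.004, -0.006 and -0.032, below the preset 0.01. A higher correlation between genes therefore does not account for those losses, and their cause was not tested. Camera with an estimated correlation gave a larger adjusted p in the simulation too, where the noise was independent between genes. There the shifted list went from 1.19e-27 to 0.000821. A call lost under this setting is thus not by itself a sign of correlated genes. With fry, 4, 20 and 20 passed. The LDL count of 68 probe sets became 45 with 2 groups alone and 22 without a variance trend. It became 36 without _s_at and _x_at probe sets, where fewer probe sets were tested and the 2 ox-LDL counts became 2957 and 2986. With 2 groups alone ox-LDL against non-treatment fell from 4982 to 4367, but ox-LDL against LDL rose from 4937 to 5815. Fewer samples thus do not account for all of these shifts. The non-treatment arrays correlated least with each other (0.952 to 0.964), and 1 spread shared by all groups does not show such a difference. The causes of these shifts and of the variance trend's effect were not tested. At an unadjusted p under 0.01 and 2-fold, the ox-LDL counts became 1485 and 1515; 2 choices changed at once, and the cause was not tested. Leaving out 1 array gave 39 to 91 probe sets and 5 to 7 lists for LDL, 3721 to 5016 and 14 to 17 for ox-LDL against non-treatment, and 3692 to 5812 and 14 to 15 for ox-LDL against LDL. The LDL count was 43 and 39 without LDL replicates 1 and 2.

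Uncalled log2 changes near 0 reversed on leaving out single arrays: PLIN2 after LDL ranged from -0.08 to 0.04, and DDIT3 from -0.11 to 0.02 after LDL, from -0.22 to 0.11 after ox-LDL, and from -0.16 to 0.17 for ox-LDL against LDL. Values this close to 0 carry no direction. Among called genes, IDI1 had adjusted p of 0.987 (LDL) and 0.276 (ox-LDL) without _s_at and _x_at probe sets, where another probe set stood for it. With the mean of a gene's probe sets LSS and SCD had 0.594 and 0.792 after LDL and VEGFA 0.0684 after ox-LDL. KLF6 had 0.475 (LDL) and 0.32 (ox-LDL), KHDRBS3 0.483, CYP1B1 0.328 and STAM2 0.802 (LDL), and GPAT3 0.111 (ox-LDL against LDL). Without _s_at and _x_at probe sets KHDRBS3 had 0.872 (LDL) and 0.0825 (ox-LDL), MYLIP had 0.247 (ox-LDL against LDL), and KLF6 and the unfolded protein list lost their ox-LDL calls. There the LDL fatty acid list had 0.855, and with the filter at the 75th percentile the NF-kB list had 0.13 and 0.123 and the immediate early list 0.134 and 0.0825 in the 2 ox-LDL comparisons.

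With the replicate number as a replicate block the counts were 64, 4749 and 4773. The labels do not say whether the numbers pair the samples, and the values showed no shared effect of the number. Deviations of same-numbered arrays correlated at -0.103 to 0.039, none of 9 pairs over 0.1, and those of other pairs at -0.06 to 0.107. Signal over background limits genes near the negative-control level. Bounds are given where all 3 arrays of a group lay below it; with 1 or 2 below, the size is uncertain.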

Other observations

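The tests of ERK, SRF and YAP targets here, with p adjusted over these 3 lists alone, were all chosen after the largest changes had been seen. They were first run on the full lists, where all 3 passed for ox-LDL against non-treatment with an estimated correlation (medians of 1.52, -0.40 and -0.51, adjusted p = 0.0104, 0.0206 and 0.0206) and SRF and YAP targets did not pass after LDL (0.945 each), and then on members that were in no fixed list and not selected by the naming rule, because some of the selected ones had prompted the tests.

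DUSP6, a feedback phosphatase of ERK signalling, was among the largest rises after ox-LDL, so a published set of 10 transcripts that track ERK output was tested. In its 8 measured members other than DUSP6 the median log2 change against non-treatment was 1.28, with 5 genes higher and none lower (camera adjusted p = 0.00115, and 0.0394 with an estimated correlation); PHLDA1 rose by log2 2.52 ± 0.23 (adjusted p = 3.84e-06) and DUSP4 by 1.67 ± 0.17 (adjusted p = 8.73e-06). These values are consistent with more active ERK signalling after ox-LDL, as a hypothesis found and tested on the same arrays and open to the same unrecorded batch. Against LDL the median of these 8 members was 1.77 (adjusted p = 0.000639, and 0.0323 with an estimated correlation), and after LDL it was -0.36 (adjusted p = 0.0104, but 0.0699 with an estimated correlation), where the full list of 9 passed (median -0.43, adjusted p = 0.00031, and 0.0205).

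The falls of TAGLN and ACTA2 raised the question of lower SRF-driven transcription. In the 11 of 14 measured members of an SRF and contractile list left by that rule, the median after ox-LDL was -0.30, with 6 lower and none higher (adjusted p = 0.000933, but 0.0757 with an estimated correlation), which leaves the question open. The fall of CCN2 raised the same question for YAP and TEAD targets: in 18 of 22 measured members left by that rule, the median was -0.28, with 9 lower and 2 higher (adjusted p = 0.00341, but 0.0757 with an estimated correlation), which is open as well.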
